A study of Mus musculus with 34 samples.

How the data were processed

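Liver RNA of 13 mice was measured on 34 in-house spotted oligonucleotide arrays, each hybridised with the RNA of 1 mouse in one dye and a universal mouse reference RNA in the other. Per the labels, 7 mice were kept at thermoneutral temperature and fed an endophyte-free fescue diet (TN, 20 arrays), and 6 were exposed to chronic heat stress for 2 weeks (HS, 14 arrays). The labels of 8 HS arrays give 34 °C, those of 7 give exposure from 27 days of age, and 5 of these give its end at 40 days. The diet of the HS mice and the hybridisation batches are not given in the sources used here, and the TN and HS labels are written in different ways. The labels of the TN arrays, as recorded here, give no age. Diet and age, where they differed, and batch therefore cannot be told apart from heat stress. The mouse was the replicate: 1 to 4 arrays of a mouse are technical replicates, and mouse F203 had 1 array. Per the series text the oligonucleotides were designed on rat sequence, so that mouse RNA was read across species and a mismatch can lower the signal of single probes. How far it did was not measured.

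The values deposited by the authors, taken here as log2 values, are log ratios made from both channels of each spot, 1 per spot and array; the authors' background correction, normalization, spot filters and log base are not given in the sources used here. As for the base, they ran from −7.64 to 7.71, too wide for log10 of a 16-bit scan, while natural logarithms could not be excluded, in which case every size printed would be on that scale. The deposited column medians ranged from −0.88 to 1.17, so the arrays had not been centred. Direction was settled from the dye labels and from a list of genes for plasma proteins made by hepatocytes. The deposited values ran as Cy5 over Cy3 on every array and had not been turned for swapped dyes. No intensities were used here, so dim spots could not be filtered, signal over background is unknown, and the precision is limited by the numbers of mice and arrays and the spread between them, and perhaps by dim spots. Of all values, 11 (0.0169%) were missing.

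The table holds 1920 spots. The platform annotation given with it listed 1090 of them, 1083 with 1 gene symbol and 7 with several, and left 830 unlisted. Spots that are unlisted or have several symbols were tested without a name, and some may be control spots. Spots of 1 gene were averaged, which gave 1019 named genes and 837 unnamed spots, 1856 features in all. The symbols are old and partly those of the rat: 942 of the named genes have a symbol that is also a mouse symbol and 77 have not (for example Cyp2c12 and Cyp2d3). They are printed as given, and which mouse transcript such a rat oligonucleotide read is not known. Members of the same family with similar sequence can share a probe's signal. Of 39 genes with several spots, 17 had spots whose difference between HS and TN differed in sign, and 7 had spots whose level differed by over 2 log2 units.

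Each array was centred on its median log ratio. Per gene, a least-squares fit of the Cy5 over Cy3 ratio on 13 mouse terms (positive where the mouse RNA was in Cy5, negative where it was in Cy3) and 1 dye term gave 1 log2 ratio of mouse liver over reference per mouse. These ratios were compared with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, two-sided, for genes with a value in at least 4 mice of each group, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05 on the adjusted p. Differences are HS minus TN in log2 units. Intervals are 95% confidence intervals of the same fit. A second limma fit had terms for heat, for the first letter of the mouse identifier (F or M) and for their interaction. The letter was used as a letter: the labels call F222 female and M233 male, but call M242 female too.

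The design, 34 gene lists and the rule for named genes were set before the data were examined. For each of the 27 lists with at least 5 measured genes, limma's camera with a preset correlation of 0.01 compared the list with all other features, with adjustment over lists. Camera with the correlation estimated from the mice, and fry, were run on the same lists. An exact permutation test of the mean over members per mouse was added after the data had been seen. No gene passed the threshold for heat, so the rule took the 10 named genes of smallest p, the members of smallest p of each list, and the 5 genes of smallest p for the letter and for the interaction. Up to 4 members per list were allowed; 4 are printed for the heat shock list and for both lists that camera called, and 2 for the other tested lists. Members of the lists of sex-biased liver genes at an unadjusted p under 0.05 for the letter were added after their values were seen. List means are printed for the heat shock list and for lists at an unadjusted camera p under 0.05.

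The procedure was tested on simulated data for HS against TN with 1846 features, of which 200 had known changes of mixed size, in 10 runs. It recovered 8.8% of 1.41-fold changes, 62.4% of 2-fold, 91.6% of 2.83-fold and 96.4% of 4-fold changes, and 2.11% of the calls were false. With no change simulated, limma with Benjamini-Hochberg adjustment called 0 features, with 4.21% of features at an unadjusted p under 0.05. The simulated median standard error was 0.268 log2 units, against 0.31 in the data, so that the recovered shares are too high for these arrays. They also hold only where 200 features change at once, which makes the adjustment more lenient. Where few genes change, a gene needs a smaller p to be called, and the recovered shares would be lower. Noise was drawn independently for each feature and array, so genes that vary together between mice were not simulated. How far the recovered and false shares carry over to these arrays is therefore not known.

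Alternatives fixed beforehand changed the centring (values as deposited, scaling to 1 median absolute deviation, quantile normalization), the dye term (plain means, only Cy3 or only Cy5 arrays), the combination of arrays (an array-level fit with mouse as a random block, weights by number of arrays), the filter on missing values, the averaging of spots, the moderation, the threshold and the mice used, each left out in turn. Further settings were chosen after seeing the data: leaving out the Cy5 array of M244 and the Cy3 array of F241, whose ratios spread most, array quality weights, and testing named genes only. The letter results were also rerun without each mouse and under scaling and quantile normalization, and the ratio direction and array spread under other centring, all likewise chosen afterwards.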

Results

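Gene expression in mouse liver was measured as the ratio of each mouse's RNA to a universal mouse reference RNA, a mixture used so that all mice can be compared with one standard. The 7 mice labelled thermoneutral (TN) were hybridised on 20 arrays, and the 6 mice under chronic heat stress (HS) on 14. Thermoneutral means a temperature that demands no extra heat loss or production. The TN labels, as recorded here, do not give the temperature itself. Of the 34 arrays, 21 held the mouse RNA in Cy5 and 13 held it in Cy3. The TN group had 3 identifiers starting with F and 4 with M, and the HS group 3 with F and 3 with M. The comparison of HS with TN asks which liver transcripts differ after 2 weeks of heat.

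Genes for plasma proteins, which hepatocytes make in large amounts, showed which way the ratios ran. On arrays with the liver RNA in Cy5, 23 to 29 of the 32 measured genes lay above the array median. With the liver RNA in Cy3, 2 to 7 of 32 did. The exact two-sided sign test gave p = 0.0201 or less on every array. Across genes, arrays of the same dye correlated at a median r of 0.72 (0.24 to 0.90 over 288 pairs) and arrays of opposite dye at −0.66 (−0.86 to −0.04 over 273 pairs). Opposite arrays of the same mouse correlated at a median of −0.70 over 21 pairs. Genes are not independent replicates.

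**Figure D1:**
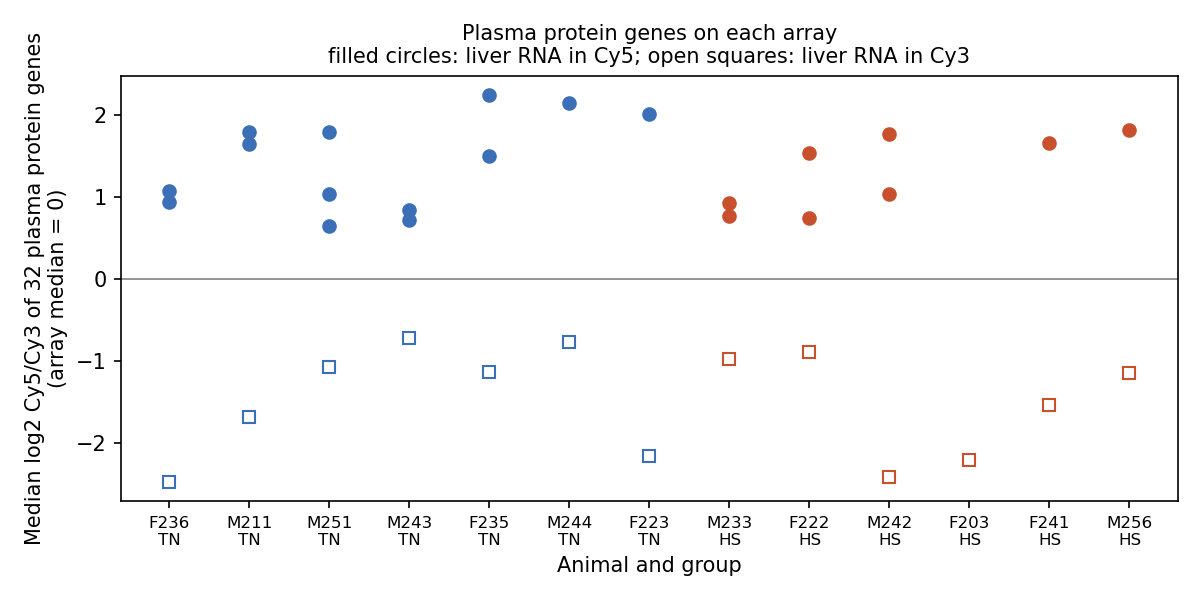
Median log2 Cy5/Cy3 ratio of 32 plasma protein genes (vertical axis, array median at 0) on each array, by mouse and group (horizontal axis). Filled circles are arrays with the liver RNA in Cy5, all above 0, and open squares are arrays with it in Cy3, all below 0.

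The spread between arrays of a mouse and the spread between mice were taken from unlike values. The SD between single arrays of a mouse, with the dye effect still in, had a median over genes and mice of 0.52 log2 units. The SD between mice had a median over genes of 0.55 in TN and 0.53 in HS. It was taken from values corrected for dye and combined over the arrays of each mouse. These SDs therefore do not show how much of the spread was technical. Across genes, deviations from the mean of arrays of that dye correlated at a median of 0.02 between arrays of the same mouse and dye, and at −0.05 between different mice. The Cy5 array of M244 (TN) and the Cy3 array of F241 (HS) stood apart. Their ratios had median absolute deviations of 2.45 and 1.90 log2 units and correlated at 0.56 and 0.53 with the other mice.

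Heat stress was not accompanied by a difference in any single gene that passed the test. Metallothionein 1 (Mt1), which binds zinc and copper and responds to stress and glucocorticoids, had the smallest p, with a mean log2 ratio of −1.93 ± 0.87 (SD, n = 7) in TN and −0.76 ± 0.62 (n = 6) in HS. Its difference of 1.17 (standard error 0.37, 95% interval 0.41 to 1.94) was positive in 6 of 6 HS mice against the TN mean, with an adjusted p of 0.999 by limma. Vamp8, a SNARE protein of vesicle fusion, followed at −1.64 (standard error 0.54), lower than the TN mean in 5 of 6 HS mice. It was 4.90 ± 0.38 in TN and 3.26 ± 1.86 in HS, and its arrays within HS mice F222 and F241 disagreed, from 2.10 to 5.81 and from −2.03 to 5.35.

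By limma with Benjamini-Hochberg adjustment, 0 of 1856 features were higher and 0 lower in HS, with a lowest adjusted p of 0.999. At an unadjusted p under 0.05 there were 45 features, 21 higher and 24 lower, where chance gives 92.8. Of the 45 features, 19 were named genes. In 0 genes did the groups not overlap, which chance gives for 0.117% of genes. The median difference was −0.01 and the median standard error 0.31. The interval excluded a 2-fold difference in either direction for 1396 features (75.2%), 804 of them named genes. Smaller differences would rarely have been detected: of 1.41-fold changes simulated for this comparison in 1846 features, 8.8% were recovered. That share holds where 200 features change at once, and would be lower where few do. For 37 of the 66 genes named for heat, leaving out 1 of the mice moved the difference by more than 1.5 times; for 13 of them leaving out F203, which had 1 array, did so.

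Among the 10 named genes of smallest p, Gnaq, the alpha subunit of a G protein that signals through phospholipase C, differed by −0.84 (standard error 0.28). Abcb6, a porphyrin transporter, differed by −0.76 (0.28). Ppp2ca, a catalytic subunit of protein phosphatase 2A, differed by −0.68 (0.30). Cpn1, the catalytic subunit of carboxypeptidase N in plasma, differed by 0.72 (0.26). In each of these, 6 of 6 HS mice lay on that side of the TN mean. Gckr, the regulator of glucokinase, differed by 0.84 (0.34), and Pcyt2, an enzyme of phosphatidylethanolamine synthesis, by 0.71 (0.30), which turned to −0.06 on the Cy5 arrays alone. Cyp2c12, a P450 with female-biased expression in rat liver, differed by −0.68 (0.28), and Robo2, an axon guidance receptor, by −0.63 (0.27). In these 4 genes, 5 of 6 HS mice lay on that side. All had an adjusted p of 0.999 by limma. The 10 genes, Mt1 and Vamp8 among them, were picked by smallest p. The side on which their HS mice lay is therefore no further evidence.

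**Figure D2:**
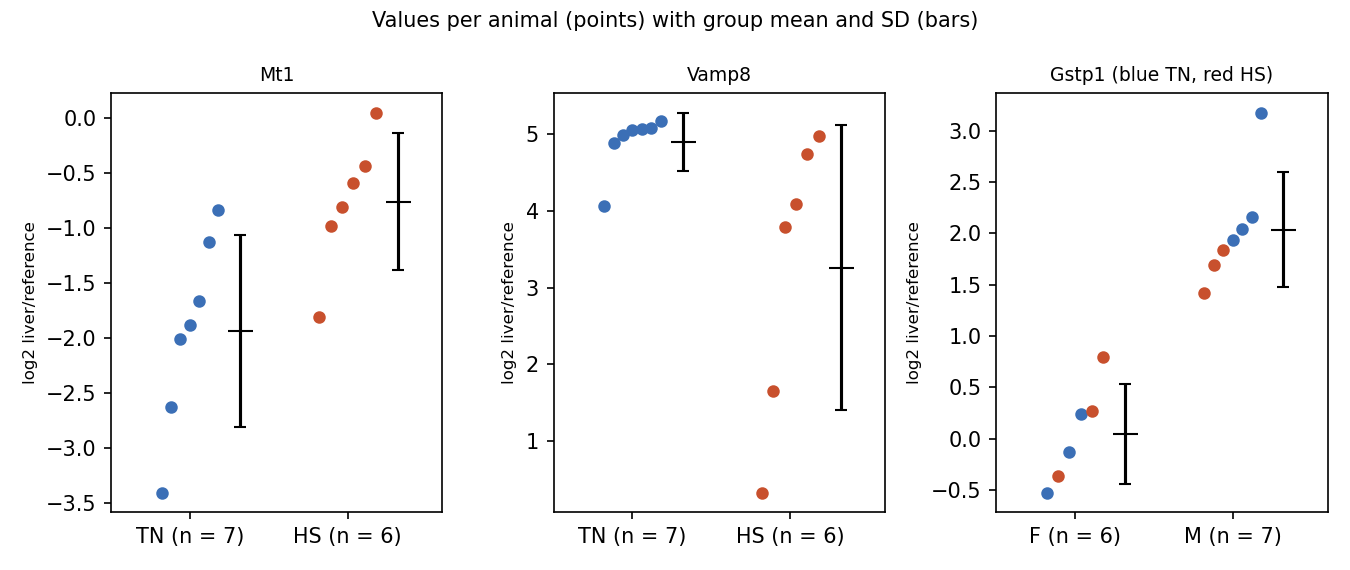
Log2 ratio of liver over reference (vertical axes) for Mt1 and Vamp8 by group and for Gstp1 by first letter of the identifier (blue TN, red HS). Points are mice and bars the mean and SD. For Mt1 the group means were −1.93 and −0.76 with overlapping mice, and for Gstp1 the highest F mouse was at 0.80 and the lowest M mouse at 1.42.

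The measured heat shock proteins and cytosolic chaperones, a class that refolds damaged proteins, showed no detectable shift. Only 10 of the 44 symbols in the list were measured, so the list does not cover a heat shock response as a whole. The 10 measured genes had a mean of −0.60 ± 0.42 (SD, n = 7) in TN and −0.58 ± 0.21 (n = 6) in HS. The mean difference was 0.02 (95% interval −0.40 to 0.45; exact permutation p = 0.922), while the median over members was −0.04, of the opposite sign, and the mean lay between −0.12 and 0.18 over the other settings. Of the members, 5 were positive, meaning here and in the other lists that the difference of HS minus TN was above 0, and 0 passed the test, and the intervals of all 10 excluded a 2-fold difference. The lens and muscle small heat shock protein Cryab differed by 0.38 (standard error 0.27), Hspa4 by 0.37 (0.29), the chaperonin subunit Tcp1 by −0.22 (0.27) and Hsp90ab1 by −0.17 (0.31). The direction of Hsp90ab1 turned to 0.005 under quantile normalization. The Cryab value averages spots at levels of 1.83 and −0.68. Camera in limma gave the list an adjusted p of 0.835.

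Across all lists, 433 list genes were measured, 6 had an unadjusted limma p under 0.05, and 0 passed adjusted over the list alone or over all features. Camera called 2 of the 27 tested lists, fatty acid synthesis and ribosomal proteins. Neither held with an estimated correlation, where the lowest adjusted p was 0.91. Fry in limma called 0 lists in one direction (lowest adjusted p 0.954) and 0 in either direction (0.968). The exact permutation test of list means called 0, with a lowest p of 0.112, adjusted 0.996.

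All 5 measured genes of fatty acid and triglyceride synthesis, of 30 symbols in the list, had a positive difference between HS and TN, none past the test. The desaturase Scd2 differed by 0.60 (standard error 0.31), Thrsp, a regulator of lipogenesis, by 0.60 (0.33), fatty acid synthase Fasn by 0.61 (0.39) and ATP citrate lyase Acly by 0.42 (0.33). The list mean was 0.33 ± 0.52 (SD, n = 7) in TN and 0.87 ± 0.62 (n = 6) in HS, a difference of 0.54 (95% interval −0.17 to 1.24; exact permutation p = 0.112). Camera gave an adjusted p of 0.00222. With an estimated correlation camera gave an unadjusted p of 0.0446 and an adjusted p of 0.91. On the Cy3 or the Cy5 arrays alone the list was not called, at 0.81 with adjusted p = 0.0654 and at 0.20 with adjusted p = 0.357.

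Of the 50 measured ribosomal protein genes, only 4 had a positive difference between HS and TN, and none passed the test. Rpl19 differed by −0.63 (standard error 0.37), Rpl5 by −0.55 (0.36) and Fau by −0.48 (0.31), while Rpl23a, the member of smallest p, differed by 0.47 (0.25). The list mean was −1.56 ± 0.41 (SD, n = 7) in TN and −1.77 ± 0.36 (n = 6) in HS, a difference of −0.20 (95% interval −0.68 to 0.27; exact permutation p = 0.365). Camera gave an adjusted p of 0.0017, and limma's adjusted p = 0.91 with an estimated correlation. Scaling all arrays to one spread turned the mean to 0.06, and quantile normalization brought it to −0.04 with an adjusted p of 0.819. Without M211, F241 or M256 the adjusted camera p was 0.421, 0.106 and 0.337. The mean itself ran from −0.29 to −0.082 with each mouse left out in turn.

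**Figure D3:**
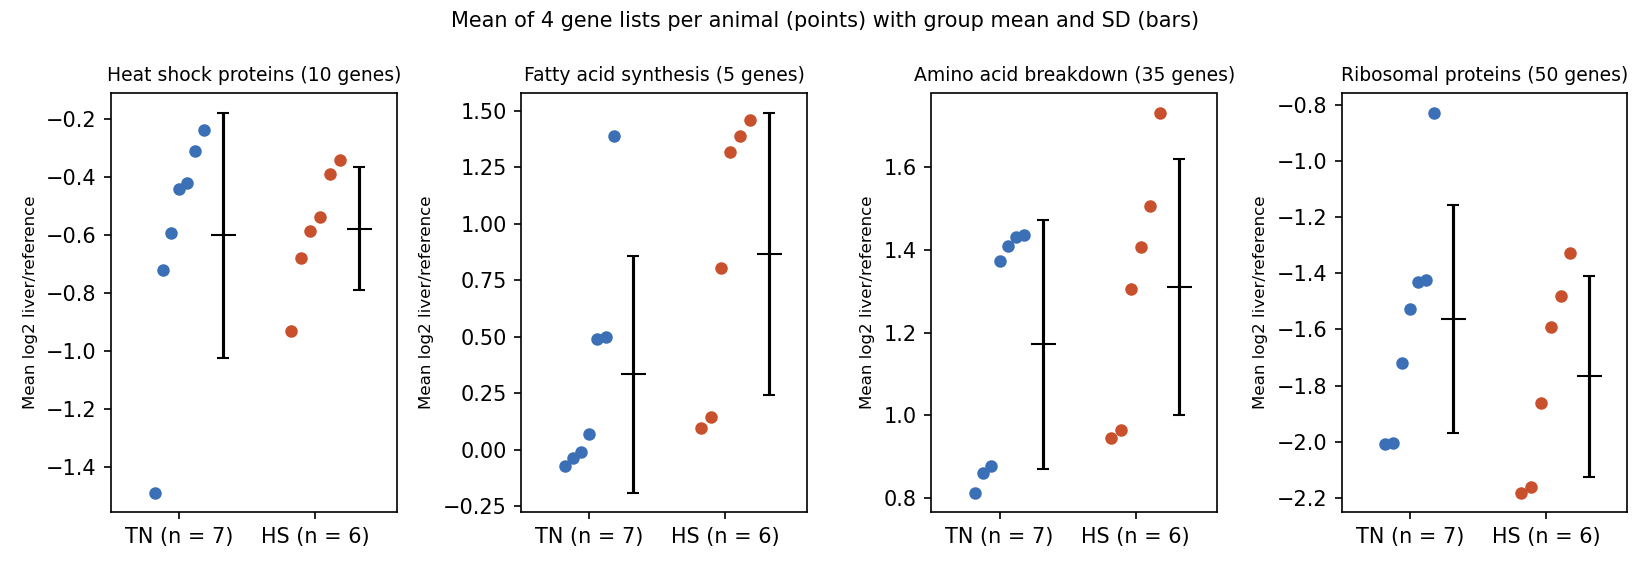
Mean log2 ratio of liver over reference per mouse (vertical axes) for 4 gene lists in TN (blue, n = 7) and HS (red, n = 6). Points are mice and bars the group mean and SD. The groups overlap in each list, with mean differences of 0.02 for heat shock proteins, 0.54 for fatty acid synthesis, 0.14 for amino acid breakdown and −0.20 for ribosomal proteins. All of these means but that of fatty acid synthesis change sign in at least one other setting.

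Other pathways of fuel metabolism had members in both directions. For amino acid breakdown and the urea cycle, 27 of 35 genes were positive and the mean difference was 0.14 (95% interval −0.24 to 0.51; exact permutation p = 0.43), with a camera adjusted p of 0.0555 and adjusted p = 0.91 with an estimated correlation. Camera called this list in 7 of 30 other settings, among them plain means of the turned arrays (0.17, adjusted p 0.0205), while scaling the arrays turned the mean to −0.10. With each mouse left out in turn the mean ran from 0.054 to 0.21, and the list was called without F236, F235, F223, M233 or F222 (adjusted p from 0.00319 to 0.0213). None of the 7 calls held in camera with an estimated correlation (adjusted p from 0.752 to 0.91). Gamt, which makes creatine, differed by 0.56 (standard error 0.27), and Pccb, a subunit of propionyl-CoA carboxylase, by 0.49 (0.30). In gluconeogenesis and glycogen 7 of 10 genes were positive (camera adjusted p 0.444 in limma), with pyruvate carboxylase Pc at 0.54 (0.24) and liver glycogen synthase Gys2 at 0.46 (0.29). In glycolysis 4 of 11 were positive (0.825), with liver pyruvate kinase Pklr at 0.84 (0.45), which was 0.38 without F203, a mouse with 1 array and the highest value of 4.56, and ketohexokinase Khk at 0.44 (0.27). In fatty acid oxidation and ketone synthesis 16 of 30 were positive (0.561), with the peroxisomal enzyme Ehhadh at 0.41 (0.26) and Cyp4a3 at 0.47 (0.33), which turned to −0.15 on the Cy5 arrays alone. In the mitochondrial respiratory chain 2 of 16 were positive (0.561), with the ATP synthase subunit Atp5pd at −0.40 (0.32) and cytochrome c, Cycs, at −0.22 (0.29).

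In cholesterol synthesis and uptake 7 of 10 genes were positive (camera adjusted p 0.561 in limma). The sterol demethylation enzyme Msmo1 differed by 0.59 (standard error 0.31) and the isopentenyl isomerase Idi1 by −0.33 (0.26). In bile acid synthesis and transport 12 of 18 were positive (0.561). The nuclear receptor Nr5a2, which also belongs to the list of nuclear receptors and liver transcription factors, differed by −0.65 (0.34), and Cyp8b1, which sets the share of cholic acid, by 0.47 (0.29). Of the transcription factor list 5 of 10 were positive (0.835), and the circadian output factor Tef differed by 0.51 (0.27). In the growth hormone, thyroid and steroid axes 7 of 10 were positive (0.561), with Hsd11b1, which regenerates active glucocorticoid, at −0.62 (0.37) and Igfbp2 at 0.43 (0.27).

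Defence and detoxification lists had no member past the test. Antioxidant defence, which holds Mt1, had 15 of 25 genes positive (camera adjusted p 0.55 in limma), with mitochondrial thioredoxin reductase Txnrd2 at 0.46 (standard error 0.27). Glutathione S-transferases had 5 of 10 positive (0.586), with Gstk1 at 0.63 (0.38) and Gsta1 at 0.44 (0.28). P450 families 1 to 3 had 11 of 18 positive (0.838), with Cyp2d3 at 0.61 (0.28) beside Cyp2c12. Spots of Cyp2e1 in this list disagreed, at −1.23 (0.51) for one and 0.01 and 0.10 for the others. Other conjugating enzymes had 20 of 28 positive (0.561), with the glucuronosyltransferase Ugt1a2 at −0.62 (0.36) and the aldehyde reductase Akr7a3 at −0.47 (0.34). Chaperones of the endoplasmic reticulum had 3 of 12 positive (0.561), with Herpud1 at 0.36 (0.26) and the disulfide isomerase Pdia3 at −0.39 (0.30). The proteasome and ubiquitin list had 16 of 29 positive (0.998), with Psmc5 at −0.49 (0.29) and Psmb6 at 0.42 (0.26).

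Among secreted proteins, 17 of 32 plasma protein genes were positive (camera adjusted p 0.838 in limma). Apolipoprotein A1, Apoa1, differed by −0.93 (standard error 0.41), or −0.49 without F203, and protein C, Proc, by 0.58 (0.33). Arrays within HS mice F222 and F241 disagreed on Apoa1, from 1.39 to 5.97 and from 1.75 to 5.89. The list mean was 0.004. When arrays were scaled to one spread it turned to −0.24, which camera called with an adjusted p of 0.0453 but limma with an estimated correlation did not (adjusted p 0.979). Acute phase genes had 11 of 16 positive (0.55), with serum amyloid P, Apcs, at 0.62 (0.38) and Orm1 at 0.43 (0.35). Orm1 turned to −0.16 on the Cy5 arrays. Complement had 4 of 8 positive (0.586), with C1s at 0.51 (0.32) and C9 at 0.29 (0.36), the latter −0.07 without M256. Apoptosis and damage response had 4 of 10 positive (0.871), with Parp1 at −0.83 (0.41) and Ccng1 at 0.65 (0.45), which turned to −0.10 with array quality weights. Cell cycle genes had 2 of 6 positive (0.561), with Tubb5 at −0.59 (0.36) and the inhibitor Cdkn1b at −0.33 (0.42), the latter 0.21 without M256.

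Markers of other cell types did not pass the test either. Kupffer cell and macrophage markers had 4 of 5 genes positive (camera adjusted p 0.55 in limma), with Slc11a1 at 0.36 (standard error 0.27) and Clec4f at 0.36 (0.28). Too few genes were measured to test the remaining lists, and in each 0 passed the limma test. Positive members were 1 of 2 for lymphocytes and antigen presentation, 1 of 4 for stellate cells and matrix, 1 of 1 for endothelium, 2 of 2 for bile duct cells, 1 of 1 for red blood cells, 3 of 3 for pancreas and fat and 3 of 3 for the circadian clock. Commonly used reference genes had 3 of 10 positive (camera adjusted p 0.55), with B2m at 0.39 (0.25) and Eef1a1 at −0.37 (0.29), the latter 0.18 with array quality weights. The list of genes higher in male mouse liver had 5 of 10 positive for heat (0.912), with Cyp2c11 at 0.44 (0.34) and Ugt2b1 at −0.37 (0.31). The list higher in females had 4 of 7 positive (0.835), with Cyp2c12 again and the hydroxyacid oxidase Hao2 at 0.40 (0.31).

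One gene differed between mice with identifiers starting with F and M. Gstp1, a pi-class glutathione S-transferase that stands in the list of genes higher in male mouse liver, was lower in F mice, at 0.05 ± 0.49 (SD, n = 6) against 2.04 ± 0.56 (n = 7) in M mice, a 3.98-fold ratio of means. The limma fit with heat as a term gave F minus M of −1.94 (standard error 0.30, adjusted p 0.00294). F mice ran from −0.53 to 0.80 and M mice from 1.42 to 3.18 without overlap. The gene was singled out as the one of smallest p among 1856 features, so this separation is no evidence apart from the adjusted p. M242, called female in one place and bearing the letter M, was at 1.69. Whether the probe tells mouse Gstp1 from its close paralog Gstp2 is not known.

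At an unadjusted p under 0.05 by letter in limma there were 62 features, where chance gives 92.8 on average. How far that count varies over reassigned letters was not measured. After Gstp1 the smallest p values belonged to Parp1 at −1.33 (standard error 0.32, adjusted p 0.367), Apcs at 1.17 (0.31, 0.711), the glucagon receptor Gcgr at 1.01 (0.29, 0.919) and thioredoxin reductase Txnrd1 at 1.09 (0.34, 0.919), none past the threshold. Of the 7 genes of the list higher in female mouse liver, 6 were higher in F mice. Their mean was 0.67 in F and 0.16 in M, and the exact permutation p was 0.0134. Hao2 differed by 0.88 (0.27), the flavin monooxygenase Fmo1 by 1.22 (0.43) and the sulfotransferase Sult2a1 by 1.03 (0.37), none past the adjusted threshold. Of the 10 genes of the male list 5 were lower in F mice, with a mean of −0.15 and a median of 0.02 of the opposite sign (exact permutation p = 0.0839). The steroid dehydrogenase Hsd3b5 differed by −0.81 (0.38).

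The heat difference itself was compared between F and M mice by the interaction. Liver fatty acid binding protein Fabp1 was 5.71 in TN and 3.06 in HS among F mice, and 4.52 and 5.60 among M mice, an interaction of −3.73 (standard error 0.81, adjusted p 0.253 by limma). Vamp8 was 5.04 and 1.93 among F mice and 4.79 and 4.60 among M mice, an interaction of −2.92 (0.81). Apoa1 had −1.86 (0.72), Nr5a2 −1.56 (0.63) and vimentin, Vim, 1.94 (0.73), and these and Vamp8 had an adjusted p of 0.998. Limma called 0 interactions, with 22 features at an unadjusted p under 0.05. Fabp1 passed without M244 (adjusted p 0.0269) and Vamp8 without F222 (adjusted p 0.0131), and arrays of HS mice F222 and F241 read Fabp1, Vamp8 and Apoa1 several log2 units apart.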

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

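The comparison of arrays within mice for Vamp8 and Fabp1, the other splits for genes under heat stress and the splits for the interaction were tests chosen after the result was seen; the splits for gene lists were chosen before.

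A mouse far from the others of its group was looked for in 152 groups of values, by its gap to the nearest mouse as a share of the group's range. In 13 groups the share was above Dixon's 95% critical value for a group of that size, where chance gives about 7.6, or 1 in 20. TN mouse M244 was set apart in 7 of the 13. It was lowest for Vamp8, at 4.06 against 4.88 for the nearest mouse (share 0.741), for Fabp1, at 2.39 against 4.92 (0.726), for Psmb6, at −1.13 against −0.39 (0.638), and for Cyp2c11, at −1.45 against −0.56 (0.612). It was highest for Hsd11b1, at 2.29 against 0.88 (0.585), and lowest for the mean of the heat shock list, at −1.49 against −0.72 (0.615). Its correlation with the other mice across genes was 0.67, against 0.83 for the nearest TN mouse (0.593). M244 has 2 arrays, of which the Cy5 array has the widest ratios of the 34 arrays, and no value for Fabp1.

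HS mouse M256 was set apart for the cell cycle inhibitor Cdkn1b, at −3.12 against −0.22 (0.836), and for the complement component C9, at 1.83 against 0.23 (0.658). Among TN mice, F235 was low for the glucokinase regulator Gckr, at −0.47 against 0.41 (0.616), and M211 was high for ketohexokinase Khk, at 1.60 against 0.69 (0.645). F223 was high for Txnrd1, at 2.06 against 1.07 (0.605), and F236 was high for the fatty acid synthesis list, at 1.39 against 0.50 (0.609).

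Vamp8 and Fabp1 had low values in HS mice with identifiers starting with F. Single arrays that read these genes differently may account for this: the range between arrays of a mouse had a median of 5.55 log2 units over both genes in F222 and F241. Taken per mouse as the median of its ranges for both genes, it was 3.68 in F222 and 7.40 in F241. Among the 9 other mice with several arrays that read both genes, this value had a median of 1.26 and was at most 2.17, in M256. Single genes could range wider there, as Fabp1 in M256 did, from 4.10 to 7.00. For Vamp8, F241 read 5.35 on its Cy5 array and −2.03 on its Cy3 array, and F222 read 5.81 on its Cy3 array and 3.34 and 2.10 on its Cy5 arrays. F203, the remaining HS mouse of that letter, had a single array, at 0.44 for Vamp8 and 2.26 for Fabp1, so that its low values have no repeat. A response to heat that depends on sex stays open and was not tested apart from the interaction.

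For the count of genes under heat stress the splits of the mice decide nothing about chance: with a real count of 0, 100 of 100 splits give at least as many by construction, and the highest other count was 0. At an unadjusted p under 0.05 the real split gave 45 features, and the other splits had a median of 60 and a highest count of 655. Why some splits gave so many was not tested. For the gene lists called by camera, 30 of 100 splits gave at least the real count of 2, with a highest other count of 10, so chance was not excluded. For the interaction, also with a real count of 0, 100 of 100 reassignments of the letters likewise decide nothing, and the highest other count was 6.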

How the results depend on the processing

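The settings without the Cy5 array of M244 and the Cy3 array of F241, with array quality weights and with named genes only, the letter results without each mouse, scaled or quantile normalized, and the array spread under other centring were tests chosen after the result was seen. In all 32 alternatives limma called 0 genes under heat stress, with lowest adjusted p from 0.697 to 1.00 and 15 to 95 features at an unadjusted p under 0.05. Of 2046 values of 66 named genes, 2036 kept their sign, 10 changed it and 0 passed the threshold. The fatty acid list was called in 28 of 30 alternatives and the ribosomal list in 22, both by camera with the preset correlation. Both calls were lost in camera with an estimated correlation (adjusted p = 0.91 for each, unadjusted p 0.0446 and 0.313). The exact permutation p was 0.112 and 0.365. The amino acid list, not called otherwise, was called in 7, 1 of them the threshold of 0.1. None of these 7 calls held in camera with an estimated correlation (adjusted p from 0.752 to 0.91). For the other 23 tested lists, 125 of 690 means changed sign, in 22 lists, and 1 passed the threshold, plasma proteins after scaling at −0.24, not called with an estimated correlation (adjusted p 0.979). Gstp1 kept its direction and call in 19 alternatives, from −2.09 to −1.79 with adjusted p from 0.000424 to 0.0428. Lists were not rerun under robust moderation or without moderation. Turning the values back was not needed, since arrays of opposite dye of the same mouse correlated at a median of −0.70. Signal over background is unknown, so what dim spots limit could not be measured. Unless named otherwise, the cause was not tested.

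With values as deposited, the heat shock list mean was −0.052 and the SD between arrays of a mouse 0.72. Scaling gave −0.10 for the amino acid list, 0.060 for the ribosomal list (adjusted p 0.225) and 1 interaction gene, Rbp4. Quantile normalization gave 1 list called, −0.036 for the ribosomal list (0.819) and 0.0052 for Hsp90ab1. The Cy3 arrays alone, with fewer arrays, called 0 lists, with 0.81 for the fatty acid list (0.0654), −0.19 for the ribosomal list (0.0501) and 0.21 for Cdkn1b. The Cy5 arrays alone called 0 lists, with 0.20 for the fatty acid list (0.357), −0.21 for the ribosomal list (0.261), −0.049 for the amino acid list, −0.084 for the heat shock list, −0.057 for Pcyt2, −0.15 for Cyp4a3 and −0.16 for Orm1. With mouse as a random block the heat shock list was −0.0012, and without the Cy5 array of M244 and the Cy3 array of F241 it was −0.089. Array quality weights called 1 list, with −0.067 for the ribosomal list, −0.035 for the amino acid list, −0.020 for the heat shock list, −0.10 for Ccng1, 0.078 for Cdkn1b and 0.18 for Eef1a1.

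With each mouse left out in turn, the lists called ranged from 1 (without M211, F241 or M256) to 3, the ribosomal mean from −0.29 to −0.082, the heat shock mean from −0.12 to 0.094, C9 from −0.068 to 0.43 and Cdkn1b from −0.48 to 0.21. C9 and Cdkn1b changed sign without M256. Genes that differed by letter ranged from 1 to 3 (without F222: Gstp1, Vamp8 and Fmo1), and interaction genes from 0 to 1 (Fabp1 without M244, Vamp8 without F222).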

Other observations

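The estimated correlation of ribosomal genes, the sex-biased lists, the Gstp1 call without single arrays and the mice left out in turn for Gstp1 were tests chosen after the result was seen; the letter reassignments, the division by slope and the gap on single arrays were chosen before.

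The 50 ribosomal protein genes, with a mean difference of −0.20 in HS, called by camera, may have been called because they vary together between mice. Allowing for their own correlation of 0.43 gave p = 0.313 in limma. Wider ratios in some mice could also contribute, but this stays undecided: dividing each mouse's ratios by its slope on the mean of the other mice left −0.12. Scaling arrays to one spread gave 0.06 and quantile normalization −0.04. Lower ribosomal protein transcripts under heat stress are thus one explanation among several that stay open.

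For the lower Gstp1 in F mice, 100 reassignments of the letters within each group were drawn, of 700 possible. Of these, 2 gave at least the real count of 1 gene, the real one included, with a highest other count of 4. Such a count was thus unlikely by chance, but chance was not excluded, and the count does not test Gstp1 itself. Leaving out each of 13 mice in turn, the highest adjusted p in limma was 0.0239. The doubted arrays are argued against as the cause, since both read Gstp1 nearer to mice of the other letter. M244 read 1.53 on its doubted Cy5 array and 2.56 on its Cy3 array. F241 read 1.63 on its doubted Cy3 array and −0.03 on its Cy5 array. Without both doubted arrays the difference was −2.06 (adjusted p 0.000489 in limma). The gap between the lowest M and the highest F mouse was then 1.10, against 0.62 with all arrays. On Cy3 arrays alone, which keep the doubted array of F241, the difference was −1.86 (adjusted p 0.0254 in limma). The gap there was 0.18, less than the SD of 0.52 between arrays of a mouse. That the letters mark sex stays open as a candidate explanation, since the higher female list in F mice had an exact permutation p of 0.0134. But the 9 genes of the male list without Gstp1 had a mean F minus M of 0.04 (exact permutation p = 0.574). Of these, 4 of 9 were lower in F mice. Cyp2c13 (0.53), Cyp2c11 (0.49) and Rup2 (0.33) lay highest, and Hsd3b5 (−0.81) and C9 (−0.28) lowest. Both lists hold rat symbols, Cyp2c12 in the female list and Cyp2c13, Cyp2c11 and Rup2 in the male list. The names of the lists need not hold for these members in the mouse. Which mouse transcripts the rat oligonucleotides of either list read is not known, so neither list decides. M242, which the labels call female, had an M-like value of 1.69. Signal shared with the paralog Gstp2 was not tested.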
